A study of Arabidopsis thaliana with 18 samples.

How the data were processed

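RNA sequencing of Arabidopsis thaliana roots was analysed in 18 libraries, 3 for each of 6 groups given by the labels: the wild-type accession Col-0 and the lines labelled suvh5 and suvh6, each without nematodes and each infected with the beet cyst nematode Heterodera schachtii. Per the labels' protocols, RNA was extracted from whole root tissue and poly(A) RNA was made into libraries that do not keep the strand. The deposited file of each library holds whole-number counts of reads per gene, which the authors did not normalise. Per the submitters' processing notes, FastQC, STAR 2.5, HTSeq 0.10.0 and DESeq were used with the genome build TAIR10. The order of these steps, their settings and the annotation release are not given in the sources used here.

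Each file lists 27416 gene identifiers and 5 summary lines of the kind HTSeq writes. Reads that fell in no gene made up 2.76% to 4.36% of all lines' counts in a library, ambiguous reads 0.259% to 0.329% and reads aligned to several places 2.29% to 3.85%. These lines were kept out of library sizes and tests. Totals over genes lay between 19.1 and 26.9 M per library, with a median of 23.8 M. At this depth a gene with 3 counts in a library stands at 0.112 to 0.157 CPM (counts scaled by library size). Reads shared by near-identical genes, such as the neighbouring pair KIN1 and KIN2 or the light-harvesting genes, may have been left uncounted or divided between them, so values of single members of such families are uncertain. Since the strand was not kept, reads of overlapping genes on opposite strands cannot be told apart.

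Gene symbols came from a reference gene table of the assembly TAIR10.1, which matched 26719 of the identifiers and gave a symbol for 10376. Because the build differs from that of the files, the table was used only for names and for which genes neighbour each other, and no coordinates are given.

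Differential expression was tested with edgeR 4.0.16 in R 4.3.3. Genes with low counts were removed with filterByExpr by group (minimum count 10 and minimum total count 15), which left 21161 genes and removed 6255. Library sizes were scaled with TMM factors. A quasi-likelihood negative binomial model with robust estimation was fitted to all 18 libraries with 1 mean per group, which leaves 12 residual degrees of freedom. The common biological coefficient of variation was 24.6%. Contrasts were infected against noninfected within each genotype, the average of those 3 contrasts, each mutant label against Col-0 within each infection state, and the difference between each mutant label's infection response and that of Col-0, which makes 10 contrasts. P-values were adjusted by the Benjamini-Hochberg method over all genes tested in a contrast, tests were two-sided, and genes with an adjusted p under 0.05 were called. Adjusted p-values of single genes below are those of edgeR's quasi-likelihood test. Values in CPM are normalised with the TMM factors and given as mean ± SD of 3 libraries. Fold changes are log2 values ± SE.

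The groups, contrasts, test, gene lists, rule for naming genes and all alternatives were fixed before the data were examined, except where a choice is said to have been made after seeing the data. The rule named, per contrast, the 10 genes with the largest increase and the 10 with the largest decrease that had a symbol, an adjusted p under 0.05, an average log2 CPM of at least 1 and, for contrasts of 2 groups, no overlap of CPM between the groups. It added SUVH5, SUVH6 and up to 4 called members of each gene list that passed its test or had at least 3 called members. The 26 lists hold hormone, defence, nutrient, cell cycle, cell wall and silencing genes, genes linked to nematode feeding sites, and markers of root cell types and green tissue. Of 511 members written, 495 were kept and 16 were dropped because the reference table gave their identifier another name. Lists of at least 3 tested members, 25 in all, were tested with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01, and again with an estimated correlation and with fry, adjusted over the 25 lists of a contrast. For each list the members called are also given when p-values were adjusted over the list alone.

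Alternatives were RLE scaling, scaling by library size alone, DESeq2 1.42.0, limma voom with sample weights, no filter on low counts, a stricter filter (CPM of at least 1 in at least 3 libraries), the replicate number as a block, fits with only the libraries of the groups compared, organelle genes left out, and each library left out in turn. After seeing the data, a fit without 2 libraries whose values ran against their labels, a set of label checks and an enrichment test of gene families by symbol (Fisher's exact test, families of at least 10 members) were added. The main test was tried on 21161 simulated genes for infection in Col-0. It recovered 41 of 100 genes changed 2-fold and 88 of 100 changed 4-fold, and called 6 unchanged genes. Limma voom recovered 42 and 85 with 5 unchanged called, and DESeq2 55 and 96 with 27. For real infection in suvh6 edgeR called 136 and voom 5417, so these rates need not hold there.

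The labels do not say whether the 3 replicates of a group came from separate plants or plates, so their spread may be technical. P-values pool spread over all 18 libraries. Replicate counts differed by far more than sampling noise (chi-square per degree of freedom 11.5 to 48.2 in Col-0, 21.5 to 165 in mutant labels), and no library was counted as a duplicate. The labels state 24 h without light at 26 °C only for infected plates, so infection cannot be separated from that step.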

Results

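Root transcriptomes of Arabidopsis were compared between 3 genotypes with and without a cyst nematode. Heterodera schachtii is a sedentary parasite that turns root cells into a multinucleate feeding site, the syncytium. SUVH5 and SUVH6 encode SET-domain enzymes that methylate histone H3, and the study asked how the transcriptomes of infected and noninfected suvh5 and suvh6 plants compare with those of wild-type Col-0. Plants were 15 days old when sampled without nematodes. Infected plants had received 100 hatched juveniles each at the age of 10 days and were sampled 5 days later. Inoculated plants spent 24 h in darkness, at 26 °C instead of 22 °C. The labels do not state whether noninfected plants did so too, so infection cannot be separated from that step. Each of the 6 groups had 3 libraries, with 19.1 to 26.9 M gene-assigned reads per library.

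The counts of both target genes went against the genotype labels. SUVH5 (AT2G35160, chromosome 2) stood at 4.59 ± 0.218 CPM in noninfected and 7.97 ± 0.838 CPM in infected Col-0 (mean ± SD, n = 3). In the libraries labelled suvh5 it was at 5.50 ± 0.315 CPM without infection and at 187 ± 60.9 CPM with infection. In the libraries labelled suvh6 it was at 164 ± 38.8 CPM without infection and at 5.41 ± 1.36 CPM with infection. SUVH6 (AT2G22740, chromosome 2) showed the mirror image, with 326 ± 220 CPM in suvh5 noninfected, 16.5 ± 1.19 CPM in suvh5 infected, 15.6 ± 3.93 CPM in suvh6 noninfected and 176 ± 22.3 CPM in suvh6 infected, against 16.4 ± 1.23 and 17.7 ± 2.86 CPM in Col-0 noninfected and infected.

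Single libraries did not overlap. SUVH5 lay between 117 and 227 CPM in the 6 libraries labelled suvh5 infected or suvh6 noninfected and at no more than 8.58 CPM in all others. SUVH6 lay between 74.8 and 484 CPM in the 6 libraries labelled suvh5 noninfected or suvh6 infected and between 11.7 and 20.7 CPM in all others. Against Col-0 of the same infection state, SUVH5 was higher in suvh5 infected (log2 fold change 4.55 ± 0.27, edgeR adjusted p = 2.43e-07) and in suvh6 noninfected (5.16 ± 0.28, edgeR adjusted p = 6.74e-08). It did not differ detectably in suvh5 noninfected (0.26 ± 0.25, edgeR adjusted p = 0.609) or suvh6 infected (-0.56 ± 0.24, edgeR adjusted p = 0.266). SUVH6 was higher in suvh5 noninfected (4.32 ± 0.49, edgeR adjusted p = 0.00129) and suvh6 infected (3.31 ± 0.47, edgeR adjusted p = 0.00806), and did not differ detectably in suvh5 infected (-0.11 ± 0.44, edgeR adjusted p = 0.915) or suvh6 noninfected (-0.07 ± 0.44, edgeR adjusted p = 0.934). The SUVH6 call in suvh6 infected was lost without Col-0 infected replicate 1 (edgeR adjusted p = 0.0673) or replicate 2 (edgeR adjusted p = 0.0780), and that in suvh5 noninfected in the fit of only the 2 groups compared (edgeR adjusted p = 0.116). Neither gene was lowered in the group named for it. Because of this, every direction given below for a mutant group belongs to the libraries as labelled and not to a known genotype. Nor can infected and noninfected libraries of a mutant label separate infection from a difference between lines.

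**Figure D1:**
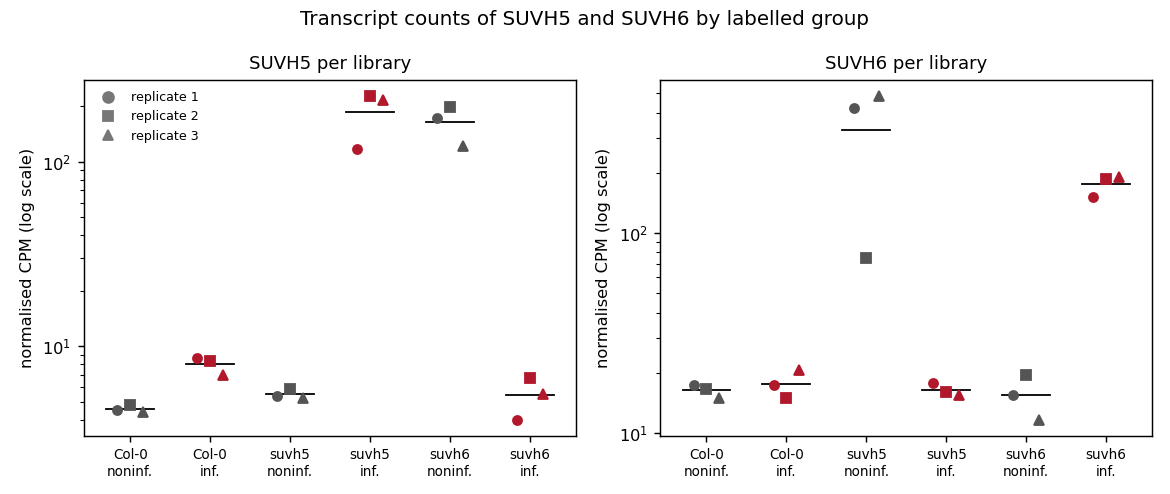
Normalised CPM of SUVH5 and SUVH6 in each of the 18 libraries on log axes (points) with group means, by labelled group. SUVH5 is at 117 to 227 CPM in the libraries labelled suvh5 infected and suvh6 noninfected, and SUVH6 at 74.8 to 484 CPM in those labelled suvh5 noninfected and suvh6 infected.

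Other genes followed the same crossed division. AT3G52220 lay at 1.80 to 8.78 CPM in the libraries labelled suvh5 noninfected and suvh6 infected, at 41.1 to 64.3 CPM in the other 6 mutant-labelled libraries and at 37.9 to 46.3 CPM in Col-0. AT2G22730, the neighbour of SUVH6, was at 5.98 to 36.2 CPM in the first set and 3.37 to 6.41 CPM in the second, so the ranges overlap. Both were chosen after their values were seen. Of 21159 genes beyond the targets, 227 separated the 12 mutant-labelled libraries completely by this division, 117 by genotype label and 74 by infection label. Chance gives 45.8 genes (0.217%) for each if replicates are treated as exchangeable. An exchange of the 2 libraries described next could lower the 117 and 74 only. A further 2 genes, also chosen after their values were seen, separated all 12 mutant-labelled libraries from Col-0. MRD1 (AT1G53480), a gene of unknown function named for its low level in a methionine over-accumulating mutant, lay at 26.9 to 41.6 CPM against 0.168 to 1.81 CPM in Col-0. AT3G29633 lay at 19.2 to 32.9 CPM against 0.337 to 0.851 CPM.

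The infection labels of 2 libraries also went against infection-associated genes. The list of cell wall loosening genes (expansins, endoglucanases and related enzymes) had a level, as the mean log2(CPM + 1) of its members centred over libraries, of 0.336 in suvh5 noninfected replicate 2, against -0.615 to -0.419 in the other 5 mutant noninfected libraries. In suvh6 infected replicate 2 it was -0.664, against 0.36 to 0.511 in the other 5 mutant infected libraries. Col-0 libraries lay at -0.241 to -0.0203 without and 0.213 to 0.493 with infection. MIOX5 (AT5G56640), a myo-inositol oxygenase of wall sugar supply, was at 43.7 CPM in that suvh5 noninfected library and at 0 CPM in that suvh6 infected library, where a count of 0 allows up to 0.13 CPM. PRX52 (AT5G05340), a class III peroxidase, was at 37.0 and 0.0423 CPM in the same libraries. Each library stayed in its labelled group, and counts of called genes without both are given for each contrast.

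**Figure D2:**
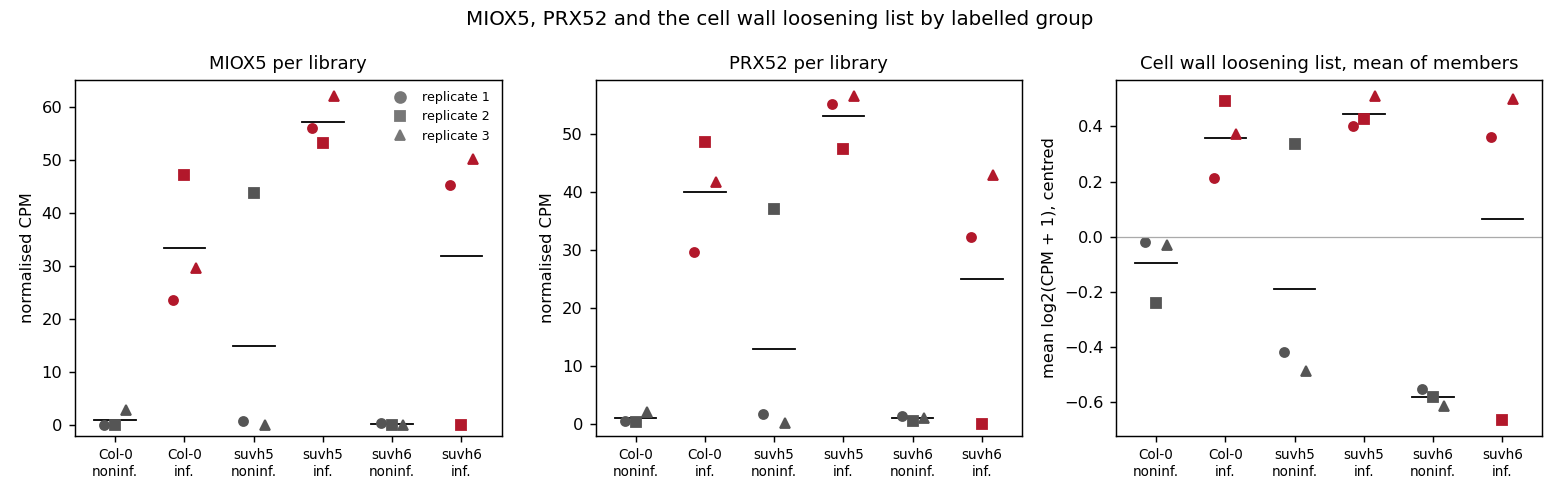
MIOX5 and PRX52 in normalised CPM and the mean centred log2(CPM + 1) of the cell wall loosening list in each of the 18 libraries (points), by labelled group. Replicate 2 of suvh5 noninfected has MIOX5 at 43.7 CPM and replicate 2 of suvh6 infected at 0 CPM.

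With infection in Col-0, gene lists for abscisic acid and cold responses, the cell cycle and green tissue passed camera upwards, and those for endodermis, root hairs, xylem, salicylate and pattern immunity passed downwards. Of these lists, 0 passed with an estimated correlation, and only part of the members of each was called. KIN2 (AT5G15970, 3.65 ± 0.39) and KIN1 (AT5G15960, 2.89 ± 0.37), small proteins induced by cold and abscisic acid, rose from 25.7 ± 1.48 to 323 ± 3.43 CPM and from 11.3 ± 1.06 to 84.1 ± 7.1 CPM (mean ± SD, n = 3). The carbonic anhydrase CA1 (AT3G01500, edgeR adjusted p = 0.0333) fell from 33.9 ± 8.22 to 2.46 ± 0.619 CPM. In all, 3317 of 21161 genes were called, 1616 up and 1701 down, of which 519 and 726 changed at least 2-fold.

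Among the largest increases (log2 fold change ± SE, n = 3 per group, edgeR adjusted p between 0.0138 and 0.0457) were PRX52 (5.35 ± 1.58), the cytochrome P450 CYP71A20 (AT4G13310, 3.90 ± 0.97) and its neighbour, the terpene synthase TPS13 (AT4G13300, 3.55 ± 0.84). IPT1 (AT1G68460, 3.58 ± 1.07) makes cytokinin precursors, SQP2 (AT5G24140, 3.31 ± 0.93) acts on squalene in sterol synthesis and BCAT2 (AT1G10070, 3.12 ± 0.75) breaks down branched-chain amino acids. The chlorophyll-binding LIL3:1 (AT4G17600, 3.76 ± 1.06) and the photosystem II antenna gene LHCB2.1 (AT2G05100, 2.93 ± 0.93) rose as well. The largest decreases (edgeR adjusted p between 0.00659 and 0.0498) included transporters and metabolic genes. HAK5 (AT4G13420, -3.00 ± 0.60) takes up potassium at low supply, SWEET14 (AT4G25010, -3.33 ± 1.05) moves sugars, MTPA1 (AT3G61940, edgeR adjusted p = 0.045) is a cation efflux protein and GDU6 (AT3G30725, -3.10 ± 0.62) belongs to a family that exports amino acids. PEN3 (AT5G36150, -3.63 ± 1.12), here a triterpene synthase, and DXPS1 (AT3G21500, -3.10 ± 0.90), of the isoprenoid precursor pathway, fell, as did the transcription factor WRKY55 (AT2G40740, -3.03 ± 0.82), the resistance protein WRR4 (AT1G56510, -2.75 ± 0.77) and the alternative oxidase AOX1D (AT1G32350, -2.72 ± 0.88).

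Marker lists of 3 root cell types passed camera downwards. Of 20 endodermis and suberin genes, 13 fell and 0 rose (18 adjusted over the list alone), with a median log2 fold change of -1.08 (camera adjusted p = 5.61e-10, and adjusted p = 0.288 with an estimated correlation). They included the suberin enzymes ASFT (AT5G41040, -1.40 ± 0.33) and GPAT5 (AT3G11430, -1.18 ± 0.31) and the transporter ABCG6 (AT5G13580, -1.38 ± 0.38). Of 13 root hair genes, 8 fell (11 adjusted over the list alone), with XTH26 (AT4G28850, -2.13 ± 0.50), EXPA18 (AT1G62980, -1.50 ± 0.31), ADF8 (AT4G00680, -1.45 ± 0.33) and COW1 (AT4G34580, -1.43 ± 0.37) as the largest (median -1.25, camera adjusted p = 1.22e-07, and adjusted p = 0.288 with an estimated correlation). Of 10 xylem genes, 6 fell (8 adjusted over the list alone), among them the lignin laccase LAC17 (AT5G60020, -1.01 ± 0.17), the cellulose synthases CESA8 (AT4G18780, -0.92 ± 0.22) and CESA4 (AT5G44030, -0.87 ± 0.21), and the xylan synthesis gene IRX9 (AT2G37090, -0.87 ± 0.18) (median -0.81, camera adjusted p = 1.54e-05, and adjusted p = 0.288 with an estimated correlation). Phloem markers did not pass the test, with 0 up and 0 down (0 adjusted over the list alone, median 0.12, camera adjusted p = 0.701). Green tissue markers moved the other way, with 11 of 26 up (18 adjusted over the list alone), for example LHCB3 (AT5G54270, 1.98 ± 0.61), LHCA1 (AT3G54890, 1.90 ± 0.49) and PSAD-1 (AT4G02770, 1.52 ± 0.36) (median 1.17, camera adjusted p = 1.1e-08, and adjusted p = 0.425 with an estimated correlation). The Rubisco small subunit RBCS1A was at 62.4 ± 15.8 CPM without and 150 ± 30.8 CPM with infection and was not called (log2 fold change 1.27 ± 0.44, edgeR adjusted p = 0.0638).

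Of the defence lists, salicylate, pattern immunity and camalexin with indole glucosinolates passed camera downwards and jasmonate did not. In the salicylate list 4 of 21 genes fell (4 adjusted over the list alone; camera adjusted p = 0.00065, and adjusted p = 0.425 with an estimated correlation), the salicylate exporter EDS5 (AT4G39030, -1.28 ± 0.24), EDS1 (AT3G48090, -0.45 ± 0.10), FMO1 (AT1G19250, -1.34 ± 0.39) and WRKY70 (AT3G56400, -1.12 ± 0.31). Pattern immunity genes included 3 decreases of 20 (3 adjusted over the list alone), in the kinase FRK1 (AT2G19190, edgeR adjusted p = 0.000944), the chitin receptor CERK1 (AT3G21630, -0.89 ± 0.11) and the co-receptor BAK1 (AT4G33430, -0.66 ± 0.15) (camera adjusted p = 0.000117, and adjusted p = 0.425 with an estimated correlation). In the camalexin and indole glucosinolate list 8 of 18 fell (10 down and 1 up adjusted over the list alone), led by CYP81F2 (AT5G57220, -2.56 ± 0.52), CYP71A12 (AT2G30750, -2.34 ± 0.46), GSTF6 (AT1G02930, -2.24 ± 0.53) and IGMT2 (AT1G21120, -2.03 ± 0.48) (camera adjusted p = 0.000136, and adjusted p = 0.288 with an estimated correlation). Lignin and flavonoid genes had 4 decreases of 20 (4 adjusted over the list alone), in CAD4 (AT3G19450, -0.82 ± 0.19), PAL4 (AT3G10340, -0.62 ± 0.14), PAL1 (AT2G37040, -0.57 ± 0.15) and PAL2 (AT3G53260, -0.46 ± 0.13) (camera adjusted p = 0.0457, and adjusted p = 0.664 with an estimated correlation).

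Abscisic acid and cold genes rose in 5 of 18 cases (8 adjusted over the list alone), including RD29A (AT5G52310, 2.73 ± 0.84) (camera adjusted p = 4.36e-05, and adjusted p = 0.108 with an estimated correlation). Of 23 genes linked to syncytia, 5 rose and 1 fell (11 and 2 adjusted over the list alone), with RAP2.6 (AT1G43160, 1.53 ± 0.40), MIOX2 (AT2G19800, 1.14 ± 0.21) and the growth-regulating factors GRF9 (AT2G45480, 1.06 ± 0.28) and GRF2 (AT4G37740, 0.75 ± 0.23) (camera adjusted p = 0.0114, and adjusted p = 0.108 with an estimated correlation). Of 32 cell cycle genes, 7 rose (9 adjusted over the list alone), such as the replication factor CDC45 (AT3G25100, 0.85 ± 0.24), the mitotic activators CDC20.1 (AT4G33270, 0.79 ± 0.17) and CDC20.2 (AT4G33260, 0.77 ± 0.20), and CYCB1;1 (AT4G37490, 0.44 ± 0.12) (camera adjusted p = 0.00065, and adjusted p = 0.425 with an estimated correlation). Of 14 nitrate genes, 2 fell (1 adjusted over the list alone), the nitrate reductase NIA2 (AT1G37130, -0.86 ± 0.15) and UPM1 (AT5G40850, -0.63 ± 0.20) (camera adjusted p = 0.0356, and adjusted p = 0.657 with an estimated correlation). The wall loosening list did not pass its test (camera adjusted p = 0.233), although EXPA1 (AT1G69530, 2.80 ± 0.68), EXPA10 (AT1G26770, 2.65 ± 0.84) and the endoglucanase CEL1 (AT1G70710, 1.83 ± 0.27) were among 4 members that rose and 2 members fell (7 and 3 adjusted over the list alone). The silencing machinery had 4 increases and 2 decreases of 40 (4 and 2 adjusted over the list alone), with SUVR2 (AT5G43990, 0.83 ± 0.17) and NRPD1 (AT1G63020, 0.55 ± 0.17) up and the demethylase DML3 (AT4G34060, -0.81 ± 0.24) down (camera adjusted p = 0.479).

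The remaining lists did not pass camera in Col-0, with calls up and down given over all genes and then adjusted over the list alone. The hormone lists were jasmonate (1 and 1, then 1 and 1, camera adjusted p = 0.078), ethylene (1 and 0, then 1 and 0, camera adjusted p = 0.685), auxin (2 and 4, then 2 and 4, camera adjusted p = 0.479) and cytokinin (3 and 1, then 3 and 1, camera adjusted p = 0.479). In the auxin list the conjugating enzyme GH3.3 (AT2G23170, 2.88 ± 0.78) rose and the influx carrier LAX3 (AT1G77690, -0.63 ± 0.14) fell, and in the cytokinin list CKX6 (AT3G63440, 0.96 ± 0.25) and ARR5 (AT3G48100, 0.53 ± 0.16) rose. The nutrient lists were phosphate starvation (1 and 3, then 1 and 4, camera adjusted p = 0.312) and iron deficiency (1 and 2, then 3 and 3, camera adjusted p = 0.916, with a median of 0.37 but a test direction of down). In the latter F6'H1 (AT3G13610, -1.68 ± 0.30), which makes coumarins, and the proton pump AHA7 (AT3G60330, -1.64 ± 0.38) fell. The others were heat (1 and 0, then 1 and 0, camera adjusted p = 0.182), the circadian clock (2 and 1, then 2 and 1, camera adjusted p = 0.479), dark and sugar starvation (1 and 0, then 3 and 1, camera adjusted p = 0.199) and aliphatic glucosinolates (0 and 0, then 0 and 0, camera adjusted p = 0.608). Of the genes held silent by DNA methylation, 2 had enough counts and neither was called, so that list had no test.

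Of 12 lists that passed camera in Col-0, 0 passed with an estimated correlation and 8 passed fry. The number of called genes was 1072, 1668 and 2603 without Col-0 noninfected replicate 1, 2 and 3. They numbered 1188, 974 and 2119 without Col-0 infected replicate 1, 2 and 3, and 18 of 88 genes named by the rule were called in each of these 6 fits, among them KIN1, KIN2, GDU6, HAK5, EDS5, FRK1, CERK1, LAC17 and IRX9. Without both libraries in doubt 4916 genes were called for infection in Col-0. Scaling by library size alone shifted the median of all genes from 0.04 to 0.23 and gave 3801 increases and 1003 decreases.

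**Figure D3:**
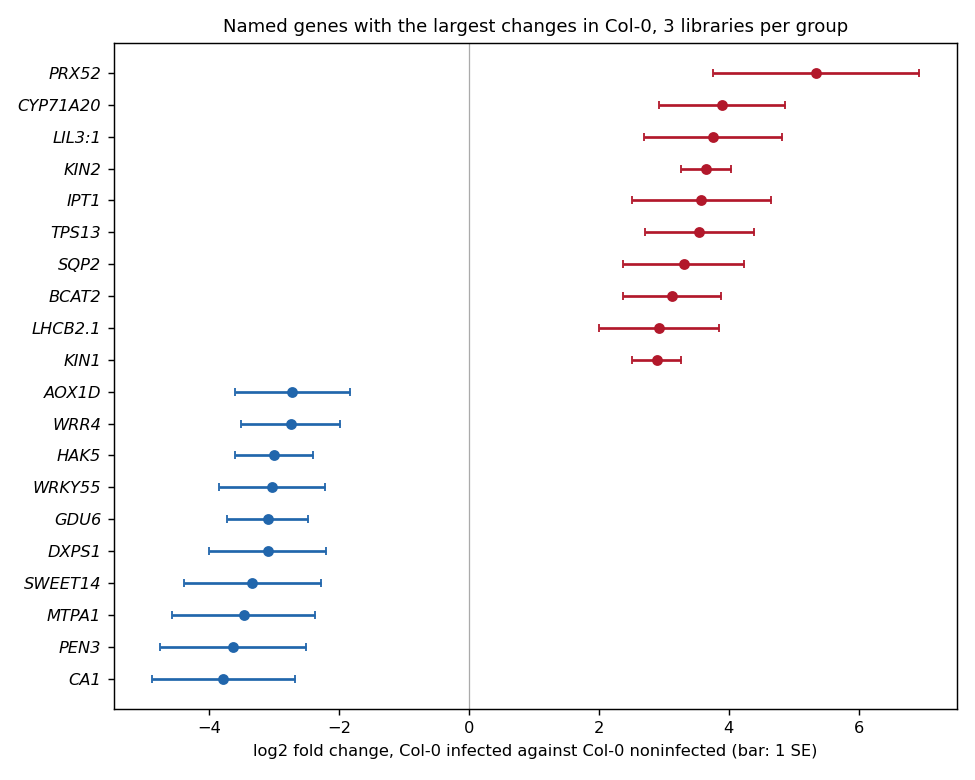
Log2 fold changes with SE bars (n = 3 per group) of the 10 genes with the largest increase and the 10 with the largest decrease named by the rule for infection in Col-0. Values run from -3.78 for CA1 to 5.35 for PRX52.

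In the libraries labelled suvh5, 336 genes were higher and 245 lower in infected than in noninfected plants. The beta-glucosidase BGLU28 (AT2G44460, 6.59 ± 1.60) rose most, and the low-sulfur response gene LSU3 (AT3G49570, 4.09 ± 0.92), the oxidase AOX1D (3.68 ± 0.90), the glucosyltransferase UGT73C7 (AT3G53160, 3.42 ± 0.40), the beta-glucosidase DIN2 (AT3G60140, 3.37 ± 0.64) and the jasmonate-regulated JRG21 (AT3G55970, 3.24 ± 0.43) rose too (log2 fold change ± SE, n = 3 per group). PEN3 rose by 4.82 ± 1.17, and FLP1 (AT4G31380, 3.86 ± 0.85) and the senescence gene SAG13 (AT2G29350, 3.44 ± 0.87) also rose. The zinc transporter ZIP12 (AT5G62160, -6.48 ± 0.96), the carbonic anhydrase CA2 (AT5G14740, -5.75 ± 1.28), the cation efflux gene MTPA1 (-5.35 ± 1.25), the nicotianamine synthase NAS3 (AT1G09240, -3.63 ± 0.92), the iron superoxide dismutase FSD1 (AT4G25100, -3.28 ± 0.57) and the citrate exporter FRD3 (AT3G08040, -2.25 ± 0.43) fell. So did GDU6 (-4.32 ± 0.81), the phosphatase PAP27 (AT5G50400, -2.39 ± 0.58) and the flowering regulator SPL3 (AT2G33810, -2.47 ± 0.62). Adjusted p-values of these genes in edgeR ran from 0.000945 to 0.0491. In total 581 genes were called, and SUVH5 and SUVH6 themselves were among them (5.09 ± 0.27 and -4.31 ± 0.49), which is the crossed pattern described above.

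In the lignin and flavonoid list 4 of 20 genes rose in these libraries, CAD5 (AT4G34230, 1.07 ± 0.19), 4CL1 (AT1G51680, 0.91 ± 0.20), HCT (AT5G48930, 0.59 ± 0.13) and 4CL2 (AT3G21240, 0.45 ± 0.11) (6 adjusted over the list alone; camera adjusted p = 3e-05, and adjusted p = 0.627 with an estimated correlation). Aliphatic glucosinolate genes passed camera downwards without any called member, over all genes or adjusted over the list alone (median -1.46, camera adjusted p = 3e-05, and adjusted p = 0.627 with an estimated correlation). That list stood at -1.76 and -1.62 in suvh5 infected replicates 2 and 3 but at 0.0162 in replicate 1. Other lists passed camera here, given with the median log2 fold change, the camera adjusted p and the adjusted p with an estimated correlation. Upwards these were abscisic acid and cold (median 0.37, 0.00543, 0.627), wall loosening (median 0.90, 0.0151, 0.627) and heat (median 0.28, 0.0464, 0.627). Downwards these were nitrate (median -0.89, 0.00519, 0.627), phloem (median -0.39, 0.0187, 0.627), salicylate (median -0.45, 0.0209, 0.627), green tissue (median -0.33, 0.0371, 0.846) and xylem (median -0.22, 0.0473, 0.627). Of 10 lists that passed camera, 0 passed with an estimated correlation and 0 passed fry. Called genes numbered 106, 1676 and 60 without suvh5 noninfected replicate 1, 2 and 3. They numbered 1036, 79 and 46 without suvh5 infected replicate 1, 2 and 3, and 3 of 29 genes named by the rule, UGT73C7, JRG21 and ZIP12, were called in each of these fits. Without both libraries in doubt 2655 were called, these 2 groups fitted alone gave 3, and library size scaling gave 283 up and 125 down.

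In the libraries labelled suvh6, phloem markers were lower in infected than in noninfected roots. The sucrose transporter SUC2 (AT1G22710, -1.72 ± 0.24), the phloem identity factor APL (AT1G79430, -0.87 ± 0.16), the sieve element protein SEOR1 (AT3G01680, -0.86 ± 0.18) and the lectin PP2-A1 (AT4G19840, -0.70 ± 0.14) fell, 4 of 7 phloem genes (4 adjusted over the list alone; camera adjusted p = 1.75e-09, and adjusted p = 0.042 with an estimated correlation). This was the only list of the 10 contrasts that kept its call with an estimated correlation. WOX4 (AT1G46480, 2.27 ± 0.47) and ANT (AT4G37750, 1.54 ± 0.30), a regulator of organ growth, rose (log2 fold change ± SE, n = 3 per group), as did the germin-like GER2 (AT5G39190, 3.13 ± 0.58), the clock gene LNK2 (AT3G54500, 2.22 ± 0.46), the phosphatase PAP28 (AT5G57140, 1.83 ± 0.24), E12A11 (AT1G18100, 1.47 ± 0.31), BBX28 (AT4G27310, 1.47 ± 0.27), the peptide gene IDL5 (AT1G76952, 1.25 ± 0.26) and SRS3 (AT2G21400, 1.22 ± 0.24). The cold-regulated COR413IM1 (AT1G29395, -2.19 ± 0.29), GCL1 (AT5G65280, -1.87 ± 0.31), ARF20 (AT1G35240, -1.59 ± 0.26), the senescence regulator NAP (AT1G69490, -1.58 ± 0.28), UBC17 (AT4G36410, -1.46 ± 0.24), HVA22E (AT5G50720, -1.46 ± 0.27), the methionine lyase MGL (AT1G64660, -1.40 ± 0.29) and the transporter ABCC4 (AT2G47800, -1.34 ± 0.24) fell. Their adjusted p-values in edgeR ran from 0.00291 to 0.0478.

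In total 136 genes were called in suvh6, 56 up and 80 down, with SUVH6 up (edgeR adjusted p = 0.00533) and SUVH5 at -4.92 ± 0.27. Iron deficiency genes passed camera upwards with 0 called members (10 adjusted over the list alone; camera adjusted p = 3.92e-07, and adjusted p = 0.324 with an estimated correlation), and so did cytokinin genes with 0 (3 adjusted over the list alone; camera adjusted p = 0.000188, and adjusted p = 0.324 with an estimated correlation) and wall loosening genes with 0 (6 adjusted over the list alone; camera adjusted p = 0.0001, and adjusted p = 0.324 with an estimated correlation). Root hair markers (median 0.48, camera adjusted p = 0.00735, and adjusted p = 0.623 with an estimated correlation) and green tissue markers (median 0.81, camera adjusted p = 2.61e-09, and adjusted p = 0.434 with an estimated correlation) also passed upwards, with 0 and 0 called members (0 and 1 adjusted over the list alone). Some further lists passed camera, with values in the order used for suvh5. Upwards it was phosphate starvation (median 0.20, 0.0423, 0.399). Downwards these were abscisic acid and cold (median -0.45, 0.0109, 0.324) and dark and sugar starvation (median -1.30, 0.0363, 0.399). Called genes numbered 19, 162 and 18 without suvh6 noninfected replicate 1, 2 and 3. They numbered 17, 1169 and 11 without suvh6 infected replicate 1, 2 and 3, and 2 of 21 genes named by the rule, PAP28 and COR413IM1, were called in each of these fits, so WOX4 and the phloem genes were not. Without both libraries in doubt 1990 were called, and these 2 groups fitted alone gave 4.

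Averaged over the 3 genotypes, the wall loosening list was 1 of 14 lists that passed camera, and 0 of them passed with an estimated correlation. MIOX5 (4.94 ± 1.14), PRX52 (4.01 ± 0.85), EXPA16 (AT3G55500, 3.41 ± 0.77), EXPA10 (2.24 ± 0.48) and EXPA1 (1.79 ± 0.38) rose, and 9 of 19 wall loosening genes rose while 1 fell (10 and 4 adjusted over the list alone; camera adjusted p = 1.28e-05, and adjusted p = 0.228 with an estimated correlation). LIL3:1, IPT1 and LHCB2.1 rose on average (2.74 ± 0.58, 2.61 ± 0.58 and 2.41 ± 0.54), which includes their rise in Col-0, and were not called in either mutant label (for LHCB2.1 0.53 in suvh5 and 3.76 in suvh6, edgeR adjusted p = 0.808 and 0.104). Also higher was FMO GS-OX2 (AT1G62540, 2.02 ± 0.49) of glucosinolate modification. Both carbonic anhydrases CA2 and CA1 fell (-3.21 ± 0.64 and -2.92 ± 0.62), as did ZIP12, MTPA1, NAS3, FRD3 and FSD1 (-3.20 ± 0.46, -2.94 ± 0.64, -2.21 ± 0.48, -1.57 ± 0.24 and -1.66 ± 0.31), LON4 (AT3G05790, -2.83 ± 0.65) and the metal-binding HIPP20 (AT1G71050, -1.13 ± 0.17). Adjusted p-values of these genes in edgeR ran from 0.00456 to 0.0401, and 696 genes were called, 379 up and 317 down.

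CA1 and CA2 were low in Col-0 and suvh5 infected libraries and in suvh6 infected replicates 1 and 3 (12.3 and 10.8 CPM for CA2), but not in replicate 2 (46.1 CPM). They were also low in suvh5 noninfected replicate 2 and suvh6 noninfected replicate 3 (4.53 and 0.835 CPM for CA1). Further lists passed camera too, with values in the order used above. Upwards these were green tissue (median 0.56, 1.08e-08, 0.35), abscisic acid and cold (median 0.30, 0.000392, 0.215), heat (median 0.38, 0.0173, 0.35) and cytokinin (median 0.19, 0.0272, 0.386). Downwards these were endodermis (median -0.35, 1.67e-05, 0.35), xylem (median -0.33, 1.67e-05, 0.26), phloem (median -0.37, 2.32e-05, 0.215), camalexin and indole glucosinolates (median -0.35, 0.000711, 0.35), root hair (median -0.36, 0.000711, 0.35), salicylate (median -0.36, 0.000815, 0.35), nitrate (median -0.21, 0.00158, 0.35), aliphatic glucosinolates (median -0.48, 0.00763, 0.527) and pattern immunity (median -0.33, 0.0246, 0.56). Called genes numbered 355, 285 and 595 without Col-0 noninfected replicate 1, 2 and 3. They numbered 341, 265 and 412 without Col-0 infected replicate 1, 2 and 3. There were 317, 1892 and 449 without suvh5 noninfected replicate 1, 2 and 3. The count was 543, 794 and 288 without suvh5 infected replicate 1, 2 and 3. They came to 387, 531 and 641 without suvh6 noninfected replicate 1, 2 and 3. The total was 429, 1435 and 344 without suvh6 infected replicate 1, 2 and 3. Of the genes named by the rule, 18 of 53 were called in each of these fits. Without both libraries in doubt 3283 were called, and library size scaling gave 978 up and 144 down.

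**Figure D4:**
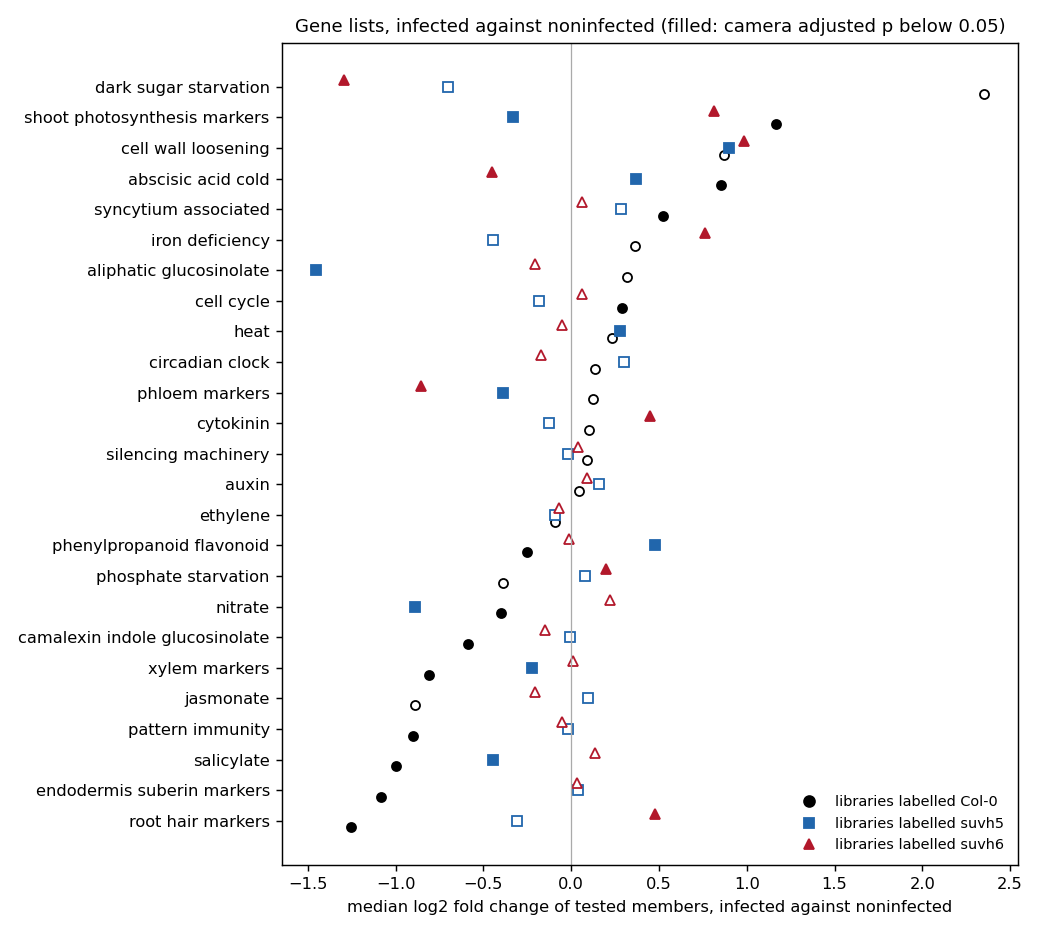
Median log2 fold change of each tested gene list for infection in the libraries labelled Col-0, suvh5 and suvh6, with filled marks for lists that passed camera at an adjusted p under 0.05. In Col-0 infection, root hair and endodermis markers have the lowest medians among its tested lists, at -1.25 and -1.08.

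Without infection, xylem and endodermis markers passed camera downwards in the libraries labelled suvh5 against Col-0, but not with an estimated correlation. MRD1 was higher by a log2 fold change of 7.04 ± 0.53 (n = 3 per group), as was its neighbour HEI10 (AT1G53490, 1.74 ± 0.26), from which unstranded counts may not separate it. KIN2 (2.05 ± 0.37), IDL5 (1.87 ± 0.27), the glutathione transferase ERD9 (AT1G10370, 1.56 ± 0.26), the defensin-like PDF2.5 (AT5G63660, 1.49 ± 0.23), the lipid transfer protein LTP5 (AT3G51600, 1.42 ± 0.25), HVA22E (1.39 ± 0.28) and PAP28 (1.36 ± 0.23) were also higher. Lower genes were BGLU33 (AT2G32860, -1.85 ± 0.36), ARF20 (-1.75 ± 0.26), AGL79 (AT3G30260, -1.52 ± 0.33), the suberin-type acyltransferase GPAT7 (AT5G06090, -1.31 ± 0.28), the fasciclin-like FLA12 (AT5G60490, -1.20 ± 0.23) of secondary walls, the channel NIP6;1 (AT1G80760, -1.20 ± 0.22), the exchanger CHX17 (AT4G23700, -1.20 ± 0.24), the ferritin FER1 (AT5G01600, -1.18 ± 0.25) and FRK1 (-1.15 ± 0.25). In edgeR the adjusted p-values ran from 1.3e-05 for MRD1 to 0.0485 for AGL79. Xylem genes had 2 of 10 lower (8 adjusted over the list alone; camera adjusted p = 1.39e-09, and adjusted p = 0.313 with an estimated correlation), and endodermis genes 1 of 20 (8 adjusted over the list alone; camera adjusted p = 2.21e-11, and adjusted p = 0.494 with an estimated correlation).

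In total 172 genes were called, 92 higher and 80 lower. More lists passed camera as well, with values in the order used above. Downwards these were camalexin and indole glucosinolates (median -0.28, 0.00205, 0.494), lignin and flavonoids (median -0.33, 0.00309, 0.532), root hair (median -0.45, 0.00385, 0.583), salicylate (median -0.49, 0.0127, 0.583), nitrate (median -0.33, 0.0194, 0.583), pattern immunity (median -0.44, 0.0194, 0.641), auxin (median -0.24, 0.0243, 0.494), jasmonate (median -0.41, 0.0256, 0.641) and phloem (median -0.36, 0.0256, 0.532). The pattern immunity level was -0.934 in suvh5 noninfected replicate 2, 1 of the libraries in doubt, against 0.503 and 0.591 in replicates 1 and 3, and without both of those libraries the list turned direction and did not pass. Called genes numbered 29, 74 and 66 without Col-0 noninfected replicate 1, 2 and 3. They numbered 59, 356 and 35 without suvh5 noninfected replicate 1, 2 and 3. In each of these fits 4 of 24 genes named by the rule stayed called, MRD1, IDL5, HEI10 and ARF20. Without both libraries in doubt 587 were higher and 970 lower, while RLE scaling gave 91 and 131 and library size scaling 418 and 59. These 2 groups fitted alone gave 4.

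In infected roots, lists of green tissue, cell cycle and phloem genes passed camera downwards in the libraries labelled suvh5 against Col-0, but not with an estimated correlation. BGLU28 (6.92 ± 1.63), the borate exporter homolog BOR5 (AT1G74810, 5.32 ± 1.23), the carbonic anhydrase BCA3 (AT1G23730, 5.32 ± 1.26), the low-sulfur response gene LSU1 (AT3G49580, 4.53 ± 1.17), AOX1D (4.49 ± 0.94), SWEET14 (4.06 ± 1.08), PEN3 (4.71 ± 1.16) and DIN2 (3.87 ± 0.65) were higher, with MRD1 at 5.25 ± 0.45 (log2 fold change ± SE, n = 3 per group). ZIP12 (-4.26 ± 0.95), the wall-membrane linker CWLP (AT3G22120, -2.68 ± 0.60), FSD1 (-2.48 ± 0.55), the nitrate transporter NRT2.6 (AT3G45060, -2.40 ± 0.55), the subtilase SBT1.3 (AT5G51750, -1.93 ± 0.29) and GATA2 (AT2G45050, -1.87 ± 0.40) were lower. So were CAB1 (AT1G29930, -2.59 ± 0.71), LHCB2.3 (AT3G27690, -2.10 ± 0.32), the chlorophyll synthesis gene PORB (AT4G27440, -1.94 ± 0.54) and the chloroplast import regulator CIA2 (AT5G57180, -2.13 ± 0.41). In edgeR the adjusted p-values of these genes ran from 5.91e-05 to 0.0435.

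Green tissue genes were lower in 10 of 26 cases (22 adjusted over the list alone), for example LHCA2 (AT3G61470, -1.85 ± 0.41), PSAD-1 (-1.64 ± 0.37) and PSBP1 (AT1G06680, -1.47 ± 0.30) (camera adjusted p = 3.91e-18, and adjusted p = 0.352 with an estimated correlation). Cell cycle genes were lower in 9 of 32 (16 adjusted over the list alone), with CYCB2;2 (AT4G35620, -0.83 ± 0.13), CYCB2;3 (AT1G20610, -0.79 ± 0.16) and the cytokinesis syntaxin KNOLLE (AT1G08560, -0.62 ± 0.15) (camera adjusted p = 1.53e-06, and adjusted p = 0.352 with an estimated correlation). Phloem genes were lower in 3 of 7 (5 adjusted over the list alone), PP2-A1 (-1.13 ± 0.14), SEOR1 (-0.99 ± 0.18) and APL (-0.73 ± 0.16) (camera adjusted p = 1.58e-06, and adjusted p = 0.223 with an estimated correlation). Pattern immunity genes were higher in 3 of 20 (3 adjusted over the list alone), FRK1 (1.32 ± 0.26), WRKY29 (AT4G23550, 0.90 ± 0.24) and CERK1 (0.63 ± 0.11) (camera adjusted p = 0.00668, and adjusted p = 0.84 with an estimated correlation). Lignin and flavonoid genes were higher in 3 of 20 (5 higher and 1 lower adjusted over the list alone; camera adjusted p = 0.000398, and adjusted p = 0.65 with an estimated correlation). Aliphatic glucosinolate genes passed camera downwards with 0 called, over all genes or adjusted over the list alone (median -1.41, camera adjusted p = 3.19e-05, and adjusted p = 0.65 with an estimated correlation). The salicylate list (1 higher and 1 lower, also adjusted over the list alone, camera adjusted p = 0.671) and the jasmonate list (0 and 1, likewise over the list alone, camera adjusted p = 0.282) did not pass.

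In total 1374 genes were called, 761 higher and 613 lower. Another list passed camera here, with values in the order used above. Downwards it was nitrate (median -0.65, 0.0256, 0.84). Called genes numbered 320, 256 and 727 without Col-0 infected replicate 1, 2 and 3. They numbered 2065, 307 and 335 without suvh5 infected replicate 1, 2 and 3. All of these fits called the same 9 of 53 genes named by the rule. The count was 2681 without both libraries in doubt.

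Without infection, SUVH5 and not SUVH6 departed from Col-0 in the libraries labelled suvh6. Their abscisic acid and cold list passed camera upwards and their salicylate, silencing and xylem lists downwards, but 0 of them passed with an estimated correlation. KIN2 was higher by 3.54 ± 0.39 and KIN1 by 2.38 ± 0.37, with ERD9 (2.83 ± 0.27), HVA22E (2.64 ± 0.29), BCAT2 (2.92 ± 0.75), LSU3 (3.03 ± 0.88), BGLU28 (5.53 ± 1.52), the glutaredoxin ROXY2 (AT5G14070, 2.58 ± 0.70) and MRD1 (7.13 ± 0.53) (log2 fold change ± SE, n = 3 per group). Lower genes were CYP96A4 (AT5G52320, -3.66 ± 0.63), ERF71 (AT2G47520, -3.62 ± 0.88), a regulator of low-oxygen responses, GDU6 (-3.44 ± 0.64), WRR4 (-3.07 ± 0.78), sks9 (AT4G38420, -3.04 ± 0.70), the amino acid transporter LHT7 (AT4G35180, -2.98 ± 0.67), GER2 (-2.91 ± 0.58), PP2-B13 (AT1G56240, -2.73 ± 0.71) and HAK5 (-2.53 ± 0.58). These genes had edgeR adjusted p-values from 7.45e-06 to 0.044.

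Salicylate genes were lower in 6 of 21 cases (10 adjusted over the list alone), including WRKY38 (AT5G22570, -2.47 ± 0.72), WRKY62 (AT5G01900, -1.94 ± 0.53) and the synthesis regulators SARD1 (AT1G73805, -2.36 ± 0.63) and CBP60G (AT5G26920, -1.55 ± 0.41) (camera adjusted p = 3.51e-06, and adjusted p = 0.483 with an estimated correlation). The silencing machinery was lower in 4 of 40 (5 adjusted over the list alone), AGO3 (AT1G31290, -2.27 ± 0.52), the remodeller CLSY1 (AT3G42670, -1.03 ± 0.18), the histone demethylase IBM1 (AT3G07610, -0.78 ± 0.12) and the DNA methyltransferase CMT3 (AT1G69770, -0.39 ± 0.11) (camera adjusted p = 0.000535, and adjusted p = 0.531 with an estimated correlation). Xylem genes were lower in 6 of 10 (9 adjusted over the list alone), with CESA4 (-0.95 ± 0.21), CESA8 (-0.93 ± 0.22) and LAC17 (-0.82 ± 0.17) (camera adjusted p = 3.51e-06, and adjusted p = 0.483 with an estimated correlation). Root hair genes were lower in 4 of 13 (7 adjusted over the list alone), led by LRX2 (AT1G62440, -1.71 ± 0.37) (camera adjusted p = 4.48e-05, and adjusted p = 0.504 with an estimated correlation). Abscisic acid and cold genes were higher in 2 of 18 (5 adjusted over the list alone; camera adjusted p = 0.000219, and adjusted p = 0.282 with an estimated correlation). The allene oxide cyclase AOC1 (AT3G25760, -3.35 ± 0.53) and the lipoxygenase LOX6 (AT1G67560, -0.97 ± 0.26) of jasmonate synthesis were lower (2 of 24, and 2 adjusted over the list alone; camera adjusted p = 0.0141, and adjusted p = 0.565 with an estimated correlation).

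In total 2069 genes were called, 1169 higher and 900 lower. Lists beyond these passed camera, with values in the order used above. Downwards these were pattern immunity (median -0.65, 0.000219, 0.531), wall loosening (median -0.64, 0.0139, 0.531) and nitrate (median -0.42, 0.0244, 0.565). Called genes numbered 605, 896 and 759 without Col-0 noninfected replicate 1, 2 and 3. They numbered 815, 1988 and 901 without suvh6 noninfected replicate 1, 2 and 3. Of the genes named by the rule, 15 of 52 were called in each of these fits. Without both libraries in doubt 3643 were called, and library size scaling gave 2180 higher and 605 lower.

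In infected roots, 97 genes differed between the libraries labelled suvh6 and Col-0, 65 of them higher and 32 lower. The xyloglucan enzyme XTH17 (AT1G65310, 1.79 ± 0.32), MYB50 (AT1G57560, 1.57 ± 0.27), the xylan glucuronyltransferase family member PGSIP4 (AT1G54940, 1.56 ± 0.26), the fucose synthesis gene MUR1 (AT3G51160, 1.53 ± 0.26), the profilin PRF4 (AT4G29340, 1.40 ± 0.24), the root growth peptide RGF7 (AT3G02240, 1.25 ± 0.20), PIT1 (AT4G02075, 1.11 ± 0.20) and PAP28 (1.61 ± 0.23) were higher, with MRD1 at 5.29 ± 0.45 (log2 fold change ± SE, n = 3 per group). COR413IM1 (-2.54 ± 0.29), the galactinol synthase GolS2 (AT1G56600, -2.04 ± 0.41), LHCB2.3 (-1.67 ± 0.31), BGLU40 (AT1G26560, -1.62 ± 0.30), the proline dehydrogenase ERD5 (AT3G30775, -1.60 ± 0.23), GCL1 (-1.49 ± 0.30), the channel MSL5 (AT3G14810, -1.45 ± 0.23), NAP (-1.35 ± 0.28), the flowering repressor MAF4 (AT5G65070, -1.34 ± 0.26) and the kinase RLK (AT5G67280, -1.30 ± 0.15) were lower. Adjusted p-values of these genes in edgeR ran from 5.46e-05 to 0.0455.

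Endodermis genes passed camera upwards with 0 called (6 adjusted over the list alone; camera adjusted p = 1.7e-09, and adjusted p = 0.316 with an estimated correlation), root hair genes likewise (8 adjusted over the list alone; camera adjusted p = 4.13e-06, and adjusted p = 0.316 with an estimated correlation). The silencing machinery passed downwards with NRPD1 (-1.01 ± 0.17) as its 1 called member (5 adjusted over the list alone; camera adjusted p = 4.13e-06, and adjusted p = 0.316 with an estimated correlation). There were other lists that passed camera, with values in the order used above. Upwards these were iron deficiency (median 0.89, 0.00214, 0.473) and cytokinin (median 0.22, 0.0303, 0.507). Downwards these were cell cycle (median -0.21, 0.000149, 0.316), phloem (median -0.47, 0.000211, 0.246), abscisic acid and cold (median -0.77, 0.000349, 0.182), syncytium-linked genes (median -0.23, 0.0194, 0.182) and green tissue (median -0.30, 0.0402, 0.736). Called genes numbered 13, 9 and 31 without Col-0 infected replicate 1, 2 and 3. They numbered 15, 1399 and 34 without suvh6 infected replicate 1, 2 and 3. In each of these fits 4 of 20 genes named by the rule stayed called, MRD1, COR413IM1, ERD5 and RLK. The count was 2340 without both libraries in doubt and 17 with these 2 groups fitted alone.

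The infection response itself was compared between each mutant label and Col-0. For suvh5, the difference was positive for PEN3 (8.45 ± 1.62), the P450 CYP716A2 (AT5G36140, 8.17 ± 2.00), BCA3 (7.60 ± 1.67), BGLU28 (7.26 ± 2.05), BOR5 (7.08 ± 1.67), SWEET14 (6.53 ± 1.48), AOX1D (6.40 ± 1.26), the ammonium transporter AMT1;5 (AT3G24290, 6.11 ± 1.87), the mitochondrial phosphate carrier PHT3;2 (AT3G48850, 5.49 ± 0.90) and LSU1 (5.39 ± 1.54), in log2 units ± SE. It was negative for TPS13 (-4.36 ± 1.12), ZIP12 (-4.10 ± 1.17), ROXY2 (-4.06 ± 0.98), the peptide gene CLE6 (AT2G31085, -3.75 ± 1.14), XTH32 (AT2G36870, -3.56 ± 0.80), CWLP (-3.40 ± 0.83), BCAT2 (-3.32 ± 1.01), GATA2 (-3.24 ± 0.56) and NRT2.6 (-2.92 ± 0.76). In edgeR these genes had adjusted p-values from 0.00413 to 0.049. The growth-regulating factors GRF9 (-2.19 ± 0.40), GRF3 (AT2G36400, -1.33 ± 0.30), GRF4 (AT3G52910, -1.21 ± 0.28) and GRF2 (-1.18 ± 0.32) were among 6 of 23 syncytium-linked genes with a negative difference, and 2 members had a positive one (9 and 2 adjusted over the list alone), although that list did not pass camera (adjusted p = 0.205).

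Lignin and flavonoid genes had a positive difference in 7 of 20 cases (12 adjusted over the list alone), with 4CL1 (1.28 ± 0.28), PAL4 (1.11 ± 0.19) and HCT (0.91 ± 0.19) (camera adjusted p = 4.16e-05, and adjusted p = 0.539 with an estimated correlation). Camalexin and indole glucosinolate genes did so in 4 of 18 (6 positive and 1 negative adjusted over the list alone), with CYP81F2 (3.40 ± 0.71) and the camalexin enzyme PAD3 (AT3G26830, 2.80 ± 0.51) (camera adjusted p = 0.00209, and adjusted p = 0.539 with an estimated correlation). In total 2296 genes were called, 1108 positive and 1188 negative. Other lists passed camera on this difference, with values in the order used above. Upwards these were endodermis (median 1.07, 4.61e-07, 0.539), pattern immunity (median 0.71, 0.00143, 0.539), root hair (median 0.71, 0.0027, 0.539) and jasmonate (median 0.84, 0.0496, 0.675). Downwards these were green tissue (median -1.43, 1.52e-08, 0.539), cell cycle (median -0.45, 0.000242, 0.539) and aliphatic glucosinolates (median -1.78, 0.00282, 0.539). Called genes numbered 973, 1427 and 2101 without Col-0 noninfected replicate 1, 2 and 3. They numbered 1068, 979 and 1678 without Col-0 infected replicate 1, 2 and 3. There were 1613, 2923 and 1155 without suvh5 noninfected replicate 1, 2 and 3. The count was 3029, 989 and 1251 without suvh5 infected replicate 1, 2 and 3. Of the genes named by the rule, 24 of 60 were called in each of these fits. Without both libraries in doubt 4008 were called, and library size scaling gave 709 positive and 1595 negative.

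For suvh6, the difference from the Col-0 response was positive for the myrosinase-like BGLU35 (AT1G51470, 4.60 ± 0.94) and BGLU34 (AT1G47600, 4.55 ± 0.98), near-identical genes, for GDU6 (4.47 ± 0.88), ERF71 (4.46 ± 1.14), WRR4 (4.35 ± 1.09), the glutamate receptor GLR2.9 (AT2G29100, 3.56 ± 0.85), XTH26 (3.53 ± 0.70), CSLB02 (AT2G32620, 3.46 ± 0.79) and GER2 (3.43 ± 0.77). It was negative for COR413IM1 (-4.87 ± 0.41), KIN2 (-4.50 ± 0.52), KIN1 (-3.55 ± 0.51), BCAT2 (-4.42 ± 1.02), TPS13 (-4.08 ± 1.12), the sulfotransferase ST2A (AT5G07010, -3.85 ± 0.51), NAP (-3.69 ± 0.40), HVA22E (-3.67 ± 0.39) and MSL5 (-3.50 ± 0.33). The edgeR adjusted p-values ran from 4.89e-05 to 0.0394. Root hair genes had a positive difference in 7 of 13 (11 adjusted over the list alone; camera adjusted p = 1.21e-08, and adjusted p = 0.223 with an estimated correlation). Phloem genes had a negative one in 4 of 7 (4 adjusted over the list alone; camera adjusted p = 0.0006, and adjusted p = 0.223 with an estimated correlation).

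Iron deficiency genes differed positively in 3 of 19 (5 adjusted over the list alone), AHA7 (2.38 ± 0.53), F6'H1 (1.88 ± 0.42) and the coumarin exporter ABCG37 (AT3G53480, 1.57 ± 0.41) (camera adjusted p = 0.00411, and adjusted p = 0.453 with an estimated correlation). In total 1663 genes were called, 845 positive and 818 negative. Several other lists passed camera on this difference, with values in the order used above. Upwards these were endodermis (median 1.02, 1.08e-06, 0.407), xylem (median 0.65, 0.0006, 0.407), salicylate (median 0.91, 0.000927, 0.453), pattern immunity (median 0.93, 0.000955, 0.479), camalexin and indole glucosinolates (median 0.58, 0.0313, 0.5), phosphate starvation (median 0.99, 0.0392, 0.407) and nitrate (median 0.52, 0.0392, 0.566). Downwards these were abscisic acid and cold (median -1.33, 1.08e-06, 0.061), cell cycle (median -0.30, 0.00972, 0.473), syncytium-linked genes (median -0.20, 0.0122, 0.113) and dark and sugar starvation (median -2.29, 0.0143, 0.38). Called genes numbered 624, 968 and 1447 without Col-0 noninfected replicate 1, 2 and 3. They numbered 632, 621 and 1240 without Col-0 infected replicate 1, 2 and 3. There were 838, 1566 and 1359 without suvh6 noninfected replicate 1, 2 and 3. The count was 836, 3282 and 668 without suvh6 infected replicate 1, 2 and 3. All of these fits called the same 21 of 55 genes named by the rule. There were 4088 without both libraries in doubt, and library size scaling gave 625 positive and 1227 negative.

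Infection calls were compared between genotypes. Col-0 and suvh5 shared 39 increases and 46 decreases, where independent lists of these sizes give 25.7 and 19.7, and 81 genes moved in opposite directions (45.7 for independent lists). Col-0 and suvh6 shared 6 increases and 9 decreases (4.28 and 6.43), with 29 opposite (10.6). The suvh5 and suvh6 responses shared 3 increases and 1 decrease, with 29 opposite (1.92), and SUVH5 and SUVH6 were among the opposite ones. The overlap of infection calls between genotypes, increases or decreases in at least 2 of them, was 102 genes, and 1008 without both libraries in doubt. In the fit of all libraries 1 gene, AT1G68470, rose in all 3, by 0.97, 0.53 and 0.68 in Col-0, suvh5 and suvh6 (edgeR adjusted p = 0.000943, 0.0401 and 0.0299, n = 3 per group).

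Differences from Col-0 were shared between the mutant labels within an infection state. Without infection, 85 genes were called in the same direction in both, where independent lists give 8.48. Simulated unchanged groups that shared their simulated controls gave a mean of 0.05 and at most 1 over 20 simulations. With infection 58 genes were shared (3.27 and, by simulation, 0). No gene was changed in the simulations, so hardly any could be called and their counts cannot show how much shared controls add. Across genes, which are not independent replicates, the fold changes correlated at r = 0.505 without and 0.558 with infection, against 0.499 and 0.496 simulated. The highest simulated correlations were 0.527 and 0.511, so the value without infection lay below the highest simulated one. The covariance was 0.187 and 0.178 against 0.0623 and 0.0618 simulated, a difference of 0.124 and 0.116. With 3 control libraries per state the controls could not be split, so part of the overlap may come from the shared controls. Calls against Col-0 in noninfected and infected roots of the same label were mostly opposite where both were called, with 29 opposite and 6 in the same direction for suvh5, and 28 and 7 for suvh6.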

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

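All tests of explanations in this part were chosen only after the results were seen, apart from the counts of other splits of the samples, the interaction tests and the list tests, which were planned. The results below stand out because the infection response of a mutant label differed from that of Col-0, by edgeR's interaction test for genes and camera for lists. All share the Col-0 libraries. Since SUVH5 and SUVH6 contradict the labels, each value belongs to the libraries as labelled.

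For suvh5, 2296 genes had a response that differed from that of Col-0. Among genes named for infection in Col-0, the difference was -2.47 for KIN2, -4.36 for TPS13, -3.32 for BCAT2, 8.45 for PEN3, 6.53 for SWEET14, 3.99 for DXPS1, 4.90 for HAK5 and 6.40 for AOX1D (log2, edgeR adjusted p between 0.00459 and 0.0481). It was 4.29 for SUVH5 and -4.42 for SUVH6 (edgeR adjusted p = 5.32e-05 and 0.00257). Median differences of lists were 0.71 for pattern immunity, 0.54 for camalexin and indole glucosinolates, -0.45 for the cell cycle, 0.76 for lignin and flavonoids, 0.71 for root hairs, 1.07 for endodermis and -1.43 for green tissue (camera adjusted p at most 0.0027, and none of them passed with an estimated correlation).

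For suvh6, 1663 genes had a response that differed from that of Col-0. The difference was -4.50 for KIN2, -4.08 for TPS13, -4.42 for BCAT2, -3.55 for KIN1, 4.47 for GDU6, 2.95 for HAK5 and 4.35 for WRR4 (log2, edgeR adjusted p between 0.000456 and 0.0402). It was -5.72 for SUVH5 and 3.38 for SUVH6 (edgeR adjusted p = 1.33e-06 and 0.0083). Median differences of lists were 0.91 for salicylate, 0.93 for pattern immunity, 0.58 for camalexin and indole glucosinolates, -1.33 for abscisic acid and cold, -0.20 for syncytium-linked genes and -0.30 for the cell cycle. They were 0.52 for nitrate, 1.44 for root hairs, 1.02 for endodermis and 0.65 for xylem (camera adjusted p at most 0.0392, and none of them passed with an estimated correlation).

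The first pattern weighed is the counts of SUVH5 and SUVH6. Reads shared between the 2 genes would raise both together, and 0 libraries had both above 3 times the highest Col-0 library. A plain loss of the transcript of the gene each line is named for would put those 12 values below Col-0, and 1 of the 12 lay below every Col-0 library. Genotype labels exchanged between suvh5 and suvh6 in 1 infection state predict other genes that follow the crossed division, and 227 genes did, against 117 that followed the genotype label. Which state would be the exchanged one cannot be read from these values, and whether the high counts come from whole or truncated transcripts was not tested.

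The second pattern is the infection-associated genes in suvh5 noninfected replicate 2 and suvh6 infected replicate 2. A difference in depth is excluded as the cause, since the former held 20.7 M and the latter 23.2 M counts. The other mutant-labelled libraries held 19.1 to 26.9 M and matched their own infection labels. Infection labels of the 2 libraries exchanged predict that both also match the other infection label over genes that played no part in the pattern. Over 21138 genes, without the cell wall list, MIOX5, PRX52, SUVH5 and SUVH6, 2 of these 2 libraries did so. They were matched against the other 10 mutant-labelled libraries, and 10 of those 10 matched their own infection label. All of those except suvh5 infected replicate 1 did so through a replicate of their own group. Their match therefore does not show that the correlation reads infection. For suvh5 noninfected and suvh6 infected replicate 2 the best Spearman correlations were 0.972 and 0.970 within the same label and 0.986 with the other. The best match of the former was suvh6 infected replicate 3 and that of the latter suvh6 noninfected replicate 2. An exchange with each other would put the latter among the suvh5 noninfected libraries, so whether the 2 libraries were exchanged with each other or each with another sample stays open. Both libraries carry high SUVH6 counts (74.8 and 186.7 CPM). No biological explanation was tested, and failed infection of 1 sample would leave the other unexplained.

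The third pattern is MRD1 and AT3G29633, which set all mutant-labelled libraries apart from Col-0. In all, 19 genes did so (2.28 by chance), 15 of them higher and 4 lower in the mutant-labelled libraries. Col-0 libraries from another seed stock or strain than both mutant lines cannot be told apart from an effect of both mutations, because every Col-0 library differs from every mutant-labelled one in genotype label.

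Other splits of the same libraries were counted for each comparison. For 7 comparisons of 3 against 3 libraries, 10 splits are too few for a share under 0.05. The real split and the highest of the others gave 3317 and 0 genes for infection in Col-0 (1 split with as many), 581 and 464 for suvh5 (1), and 136 and 1070 for suvh6 (2). They gave 172 and 0 for suvh5 against Col-0 noninfected (1), 1374 and 0 infected (1), 2069 and 0 for suvh6 noninfected (1), and 97 and 0 infected (1). The split with 1070 genes exchanges suvh6 noninfected replicate 3 with suvh6 infected replicate 2, which points to a structure of the samples. For the infection response averaged over genotypes, 4 of 100 splits, the real one included, gave as many genes as the real 696. The highest other gave 1523. This share is under 0.05, but a structure of the samples cannot be excluded. For the differences in response, 1 of 100 splits gave as many genes in each case, with 465 as the highest other against 2296 for suvh5 and 870 against 1663 for suvh6, and chance can be excluded.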

How the results depend on the processing

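The fit without the 2 libraries in doubt was chosen after seeing the data, and all other settings were planned. The direction of each named gene that was called was kept in every setting, and SUVH6, where it was not called, changed sign in some, while some named results crossed the threshold: of 475 pairs of a named gene and a contrast, 475 kept their side of the threshold under the stricter filter, 463 under RLE scaling, 419 without a filter, 393 under library size scaling, 352 with fits of the groups compared alone and 323 with the replicate block. DESeq2 kept 472, limma voom 466 and the fit without the 2 libraries in doubt 471. Over all fits that left out 1 library, 2446 such results kept their side and 1777 lost their call. Counts of called genes stayed within 1.5 times under RLE scaling, without a filter and under the stricter filter. Leaving out organelle genes removed nothing, as none had counts, and so tests nothing. Limma voom gave 9544 called genes for infection in Col-0, 5024 in suvh5, 5417 in suvh6 and 5992 on average. Against Col-0 it gave 3710 for suvh5 noninfected, 6789 infected, 8867 for suvh6 noninfected and 4968 infected, and 7321 and 8622 for the differences in response of suvh5 and suvh6. In the same order DESeq2 gave 1460 for infection in suvh5, 709 in suvh6 and 1671 on average, then 1046, 2487, 3423 and 846 against Col-0, and 3473 and 2860 for the responses. Without both libraries in doubt the counts were 2655, 1990 and 3283 for infection in suvh5, in suvh6 and on average, 1557, 2681, 3643 and 2340 against Col-0, and 4008 and 4088 for the responses. With fits of the groups compared alone, which leave fewer degrees of freedom, they were 6742 for infection in Col-0, 3 in suvh5, 4 in suvh6, 4 and 2731 for suvh5 against Col-0 noninfected and infected, and 17 for suvh6 infected. SUVH6 in suvh5 noninfected then had 4.29 and lost its call. The replicate number as a block, which the labels do not say pairs samples and of which 0 of 15 group pairs showed a trace in all 3 numbers, gave 269, 44 and 377 for infection in suvh5, in suvh6 and on average, and 82, 1366 and 41 for suvh5 noninfected, suvh6 noninfected and suvh6 infected against Col-0. Library size scaling gave 86 for infection in suvh6, 1122 on average and 477 for suvh5 against Col-0 noninfected. The cause of these changes was not tested.

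The overlap of infection calls between genotypes (102 calls shared by at least 2) became 9 at an adjusted p under 0.01, 340 with DESeq2, 2673 with limma voom, 59 with the block and 1008 without both libraries in doubt. The overlap of suvh5 and suvh6 calls against Col-0, noninfected, (85) became 302 with library size scaling, 482 with DESeq2, 2210 with limma voom, 41 with the block and 647 without both libraries. The overlap of suvh5 and suvh6 calls against Col-0, infected, (58) became 37, 403, 2524, 18 and 897 in that order. Over all contrasts, 1 gene list passed with an estimated correlation and 37 with fry. Without both libraries in doubt, 211 list results kept their side of the threshold, 22 lost their call, 16 gained one and 1 reversed. The pattern immunity list in suvh5 against Col-0 noninfected passed camera downwards (adjusted p = 0.0194, and adjusted p = 0.641 with an estimated correlation), and without both libraries in doubt its direction turned and it no longer passed (adjusted p = 0.815). Leaving out each library in turn, counts ranged from 974 to 2603 for infection in Col-0, 46 to 1676 in suvh5, 11 to 1169 in suvh6 and 265 to 1892 on average. They ranged from 29 to 356 for suvh5 against Col-0 noninfected, 256 to 2065 infected, 605 to 1988 for suvh6 noninfected and 9 to 1399 infected, and from 973 to 3029 and 621 to 3282 for the responses. SUVH6 in suvh6 infected ranged from 3.21 to 3.44.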

Other observations

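Gene families by symbol were tested for an excess of called genes only after the results were seen (Fisher's exact test, adjusted over 274 tests). Members were treated as independent, and neither their correlation nor leaving out a library was tested, so p-values may be too small. The first families are for infection in Col-0. Fasciclin-like arabinogalactan proteins had 8 of 16 members down (adjusted p = 0.00838), including FLA12 (-1.32 ± 0.23), FLA11 (AT5G03170, -1.12 ± 0.18) and FLA18 (AT3G11700, -1.04 ± 0.17). Laccases, which polymerise lignin, had 6 of 13 down (adjusted p = 0.0268), with LAC13 (AT5G07130, -1.61 ± 0.41), LAC2 (AT2G29130, -1.44 ± 0.37) and LAC5 (AT2G40370, -1.26 ± 0.30), and irregular xylem genes 6 of 10 (adjusted p = 0.00838), with IRX6 (AT5G15630, -0.80 ± 0.18) and CESA7 (AT5G17420, -0.74 ± 0.24). Genes named CRK, a symbol of cysteine-rich receptor-like kinases that CDPK-related kinases also carry, had 10 of 27 down (adjusted p = 0.00838), among them the receptor-like CRK5 (AT4G23130, -1.99 ± 0.42), CRK40 (AT4G04570, -1.65 ± 0.41) and CRK11 (AT4G23190, -1.60 ± 0.47). Calcium-dependent protein kinases had 9 of 25 down (adjusted p = 0.0133), among them the immune kinases CPK4 (AT4G09570, -0.81 ± 0.18), CPK5 (AT4G35310, -0.57 ± 0.11) and CPK6 (AT2G17290, -0.73 ± 0.19). Genes named RPL, ribosomal proteins of the large subunit in chloroplasts or cytosol, had 8 of 21 up (adjusted p = 0.00938), such as RPL15 (AT3G25920, 1.01 ± 0.17) and RPL12-C (AT3G27850, 0.90 ± 0.14).

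In infected roots labelled suvh5, tau-class glutathione transferases had 11 of 26 members higher than in Col-0 (adjusted p = 8.16e-07), including GSTU10 (AT1G74590, 2.06 ± 0.49), GSTU22 (AT1G78340, 1.65 ± 0.37), GSTU5 (AT2G29450, 1.48 ± 0.26), GSTU9 (AT5G62480, 1.43 ± 0.28) and GSTU8 (AT3G09270, 1.16 ± 0.24). In noninfected roots labelled suvh6, laccases had 6 of 13 lower (adjusted p = 0.00462), with LAC8 (AT5G01040, -2.14 ± 0.55) and LAC3 (AT2G30210, -1.14 ± 0.34). Ribosomal proteins of the large subunit had 7 of 21 higher and genes named RPS, a symbol of the small subunit that resistance genes also carry, 7 of 24 (adjusted p = 0.00633 and 0.011), among them RPL16A (AT2G42740, 0.83 ± 0.18) and RPS13A (AT4G00100, 0.63 ± 0.15).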
